A study of Mus musculus with 6 samples.

How the data were processed

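RNA was measured by sequencing in 6 libraries of mouse splenic plasma cells, 3 from cells sorted as IgM-positive and 3 from cells sorted as IgG1-positive. Per the labels' protocols, total RNA was purified with a column kit for small inputs, full-length cDNA was made with the SMART-Seq HT kit and libraries were prepared by Nextera XT tagmentation. Per the submitters' processing notes, the tools were TopHat2 2.1.1, Bowtie2 2.3.5.1, Cufflinks 2.2.1 and Cuffdiff, and the build was mm10. The annotation and the scaling between libraries are not given in the sources used here. The deposited values were FPKM (fragments normalised to transcript length and to mapped depth), per the file headers, with 1 value per gene symbol and library for 24346 symbols. FPKM divides by transcript length and by depth, so a change in library composition or in how evenly long transcripts were covered moves the values. Read counts were not used here.

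The FPKM were analysed as deposited, with no further scaling. Genes with an FPKM of at least 1 in at least 3 of the 6 libraries were tested, which left 9087 genes. Values were transformed to log2(FPKM + 1), and the fold changes are on that scale, which understates the change of low genes. IgG1 was compared with IgM with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The 35 fixed gene lists, of which 25 had at least 5 tested members, were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists. Single values per library were compared by two-sided exact permutation tests, whose smallest possible p with 3 against 3 is 0.1. The labels do not say whether the 3 libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be partly technical.

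The groups, tests, gene lists, alternatives and the rule for named genes were set before the data were examined. The rule took, per direction, the 12 genes with the largest log2 fold change among those with adjusted p under 0.05, a mean FPKM of at least 5 in the higher group and no overlap between the groups. It left out immunoglobulin segments and predicted, Rik, Mir, Snor and LOC symbols. It then took up to 4 members per direction of each list past the threshold or, in a list with none, up to 2 members with the highest mean. In the report Slamf7, Xbp1, Sdc1, Mzb1, Hspa5, Pdia4, Dnajb11, Sec11c, Ifi27l2a and Cd79a fall outside the rule and were chosen after their values were seen, and 1 gene that the rule took is not reported here. Ighm and Ighg1 were also in the rule, as checks of the sort, and the share of immunoglobulin transcripts was planned. Of the symbols analysed here 0 named an immunoglobulin chain, so neither gene was analysed here and the immunoglobulin share could not be computed. The share of Jchain was computed in its place. The isotype of each library was taken from its label and was not checked.

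Transcript length and GC content were the medians over the GENCODE vM21 basic transcripts of each symbol. These were found for 95.7% of all symbols and 96.5% of the tested genes. GENCODE vM21 describes GRCm38, the assembly that mm10 names, and the coordinates come from it. Named genes whose exons overlap those of another protein-coding gene on either strand numbered 11 of 101, among them Txndc5, Gapdh, Ndufb8, Mef2b and Tpi1. The values of these genes are uncertain to that extent, since no source used here says that strand was used. Of the ribosomal protein genes, 60 have an annotated pseudogene copy named after them, so their values depend on how reads with several matches were assigned.

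Depth was not given as counts. Low FPKM values multiplied by transcript length piled up at a smallest step, taken as the value of 1 fragment. That step gave an estimate of 16200000, 16400000 and 17900000 fragments for IgM libraries 1 to 3 and 15600000, 15400000 and 15600000 for IgG1 libraries 1 to 3. These are approximate, since the authors' transcript lengths were not used here, and they would be equal by construction if the authors scaled the libraries to a common size.

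The procedure was tested on simulated values for the 9087 genes of the IgG1 against IgM comparison, with 200 genes changed. Of 50 genes changed by a log2 of 0.5, 1, 2 and 3 it recovered 22%, 56%, 94% and 100%, with 9 false calls among 145. The changed genes were drawn only from those with a mean log2(FPKM + 1) above that of an FPKM of 5. The noise was normal and independent between genes, with no length trend. These shares therefore do not cover lower genes or libraries with such a trend. The alternatives, whose effects are given in the closing section, were pseudocounts of 0.1 and 5, no filter, a filter at 5, median centring, quantile normalization, rescaling without Jchain, no intensity trend, robust moderation, array weights, a replicate block and leaving out each library. For the lists they were an estimated correlation and the rotation test fry. A length and GC correction (natural splines per library with 4 degrees of freedom each, fitted on genes outside the lists) and cyclic loess normalization were added after the data were seen. A further simulation put a length trend in the IgG1 libraries alone, with no changed genes outside the proteasome list. It called 936 of 9087 genes uncorrected and 22 of 8765 after the correction, which returned 0.61 for a list shifted by 0.6. The simulated trend was linear in the log of the lengths that the correction used, with no GC part. The result therefore does not cover trends of another form or other transcript lengths.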

Results

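The libraries came from congenically marked B1-8 B cells, which carry a knocked-in heavy chain that recognises the hapten NP, after transfer into C57BL/6J hosts. The hosts were immunised with NP coupled to chicken gamma globulin in alum, and at day 7 donor-derived splenic plasma cells were sorted by isotype. The design holds a single comparison, of 3 IgG1 libraries with 3 IgM libraries, which asks how plasma cells that have switched isotype differ in gene expression from those that have not. Each library held FPKM for 24346 gene symbols. Between 12159 and 12560 symbols were listed at 0 in the IgM libraries and between 12896 and 13481 in the IgG1 libraries (exact permutation p = 0.1, the smallest possible). Of the genes tested, 27 to 60 were at 0 in each IgM library and 74, 243 and 288 in IgG1 libraries 1 to 3. The IgG1 libraries agreed less with each other (Pearson r 0.930 to 0.949) than the IgM libraries did (0.966 to 0.972), and pairs of an IgG1 and an IgM library ranged from 0.917 to 0.960. On the first principal component (40.2% of the variance) IgM libraries 1 to 3 lay at -33.8, -20.7 and -24.2. IgG1 libraries 1 to 3 lay at 2.09, 24.0 and 52.6. This order of the libraries was also that of the correlation of their deviations from the gene means with transcript length. Spearman rho was 0.30, 0.15 and 0.29 in IgM and -0.15, -0.18 and -0.24 in IgG1 libraries 1 to 3. On the second component (25.9% of the variance) IgG1 libraries 2 and 3 lay at opposite ends. Values below are mean FPKM ± SD with n = 3 libraries per group, and log2 fold changes are IgG1 minus IgM of FPKM + 1, with limma's standard error (SE) and adjusted p.

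Tnfrsf17, which encodes the plasma cell survival receptor BCMA, was 7.61-fold lower in IgG1 than in IgM plasma cells, at 81.9 ± 14.8 against 623 ± 79.0 (log2 fold change -2.92, SE 0.15, adjusted p = 1.23e-06). Txndc5, a protein disulfide isomerase of the endoplasmic reticulum (ER), was 3.83-fold lower, at 1174 ± 74.6 against 4492 ± 258 (-1.94, SE 0.10, adjusted p = 1.23e-06). Ptpn6, which encodes the phosphatase SHP-1, was 5.11-fold lower, at 8.91 ± 1.77 against 45.6 ± 2.28 (-2.25, SE 0.24, adjusted p = 0.00212). Higher in IgG1 cells were the chemokine receptor gene Cxcr3 (86.0 ± 20.6 against 23.3 ± 11.6), the anti-apoptotic genes Mcl1 (110 ± 11.6 against 38.6 ± 25) and Bcl2l1 (44.9 ± 11.7 against 19.7 ± 3.07), and the glucosidase gene Mogs (117 ± 43.4 against 25.5 ± 11.9). Of these, Mogs kept adjusted p under 0.05 with limma when any 1 library was left out. Cxcr3, Mcl1 and Bcl2l1 did not (largest adjusted p 0.0505, 0.0688 and 0.101). In GRCm38, Tnfrsf17 lies on chromosome 16 from 11313812 to 11320074, Txndc5 on chromosome 13 from 38500079 to 38528824, Ptpn6 on chromosome 6 from 124720707 to 124738714 and Cxcr3 on chromosome X from 101731535 to 101734269, each annotated as protein-coding.

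**Figure D1:**
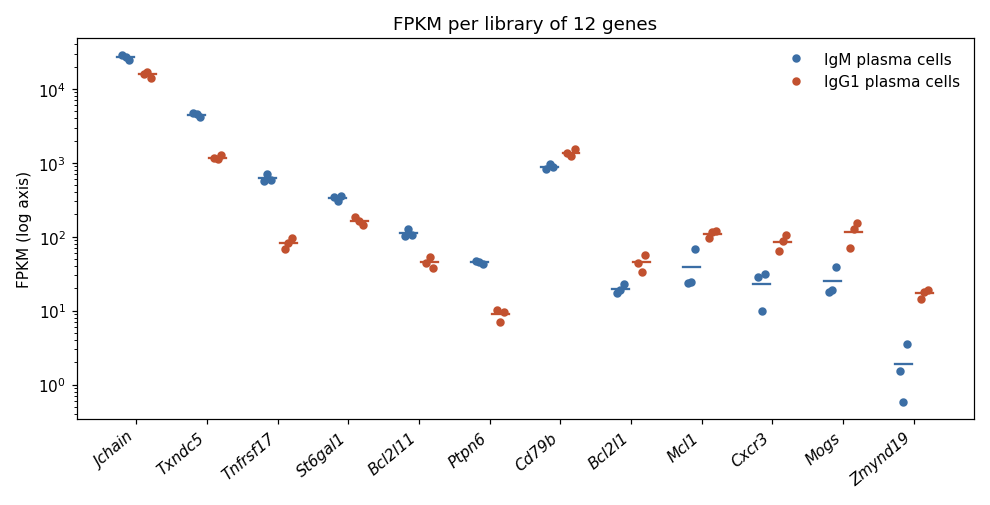
FPKM on a log axis for 12 genes in each of the 3 IgM (blue) and 3 IgG1 (orange) libraries, with a short line at each group's mean. For Mcl1, IgM library 3 (67.5) lies closest to the IgG1 libraries.

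Of 9087 genes tested, 387 were higher and 160 lower in IgG1 cells, and 86 and 86 of them changed at least 2-fold. Higher calls made up 70.7% of the total. That share was 80.6% after median centring, 48.5% after quantile normalization and 31.6% after rescaling each library to the same sum without Jchain, which moved the median of all genes from -0.05 to -0.26. Without the intensity trend 3 genes were higher and 5 lower, and without the filter 2 and 4. Tnfrsf17, Txndc5 and Ptpn6 were the 3 genes called in the same direction in all 19 alternatives of the gene test. Refitted without IgM library 1, 2 or 3, the test called 78 higher and 30 lower, 324 and 84, and 185 and 45, of which 108, 361 and 198 were among the 547 calls of the main fit. Without IgG1 library 1, 2 or 3 it called 394 and 251, 110 and 64, and 121 and 79, of which 446, 156 and 187 were among them. In all 6 of these fits 102 of the calls remained.

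The libraries also differed in how expression followed transcript length. The shortest 20% of the tested transcripts lay above their gene means in each IgG1 library (median 0.11 to 0.21 on the log2 scale) and below in each IgM library (-0.05 to -0.18), and the longest 20% went the other way. Genes higher in IgG1 had a median transcript length of 980 nt and a median GC content of 54.5%, genes lower in IgG1 3142 nt and 47.0%, and all tested genes 2488 nt and 50.4%. With each library's length and GC trend removed, a correction chosen after the data were seen, 189 genes were higher and 81 lower, and 225 of the 530 calls with a known length remained. Of the 305 that ended, 223 had become smaller by at least their SE in the main fit, 76 by less than that, and 6 were as large or larger. Corrected values are given beside the groups that follow.

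**Figure D2:**
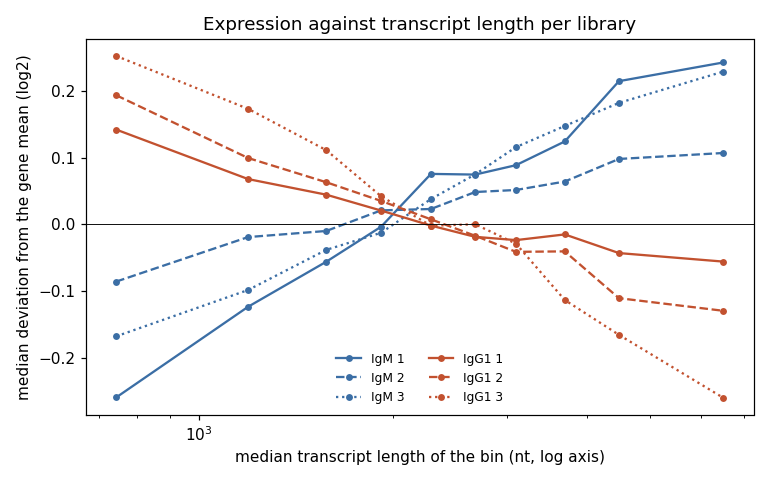
Median deviation of each library from the gene means (log2, vertical axis) in 10 equal bins of the tested genes by transcript length (nt, log horizontal axis). The 3 IgG1 libraries (orange) fall and the 3 IgM libraries (blue) climb with length, and IgM library 1 and IgG1 library 3 are the extremes.

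Plasma cell identity genes were lower in IgG1 cells as a group, with 7 of 20 tested members lower and 0 higher (median -0.38, camera adjusted p = 0.000796). With an estimated correlation the list's adjusted p was 0.24. That estimate (0.00946) was close to the preset of 0.01, so it does not by itself explain the higher adjusted p. Adjusted over the list alone, 10 were lower and 1 higher. Besides Tnfrsf17, the members past the threshold were Prdm1, which encodes the plasma cell regulator Blimp-1 (21.3 ± 4.04 against 44.3 ± 8.09), Irf4 (55.3 ± 3.61 against 92.3 ± 5.19), Cd28 (34.3 ± 5.29 against 62.1 ± 7.57), Slamf7, Tnfrsf13b, which encodes the receptor TACI (122 ± 25.2 against 193 ± 26.1), and Jchain. Jchain, the joining chain of polymeric antibody, was at 15751 ± 1406 against 26835 ± 1900 (-0.77, SE 0.10, adjusted p = 0.00389). It made up 1.79 ± 0.205% of summed FPKM in IgG1 and 3.52 ± 0.345% in IgM cells (exact permutation p = 0.1, the smallest possible). Xbp1 (6636 against 5580), Sdc1 (532 against 494) and Mzb1 (15063 against 13319) had adjusted p of 0.136, 0.695 and 0.356. The median of the list was -0.20 after the length and GC correction, under which Tnfrsf17 (-3.11), Jchain (-0.70), Tnfrsf13b (-0.80) and Slamf7 (-0.56) kept adjusted p under 0.05, while Prdm1 (-0.72, adjusted p = 0.0816), Irf4 (-0.40, 0.169) and Cd28 (-0.47, 0.233) did not. These 3 had been at -1.02, -0.73 and -0.84 (SE 0.22, 0.15 and 0.19 before and 0.20, 0.14 and 0.20 after), so each became smaller by more than its SE. Of the 7 calls, those of Tnfrsf17 and Jchain held when any 1 library was left out.

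ER chaperone and unfolded protein response genes were also lower as a group, with 10 of 34 members lower and 0 higher (median -0.26, camera adjusted p = 1.35e-06; adjusted p = 0.265 with an estimated correlation). Adjusted over the list alone, 16 were lower and 2 higher. The members past the threshold included Txndc5, the co-chaperone gene Dnajc3 (160 ± 45.2 against 290 ± 7.28), the oxidase gene Ero1lb (41.0 ± 6.28 against 75.9 ± 12.7) and the stress sensor gene Atf6 (35.3 ± 6.68 against 59.6 ± 7). The major chaperone gene Hspa5 was at 3665 against 4604 (-0.35, adjusted p = 0.135). The list's members had a median length of 2557 nt, and after the length and GC correction the list's median was -0.18 and Txndc5 (-1.87), Pdia4 (-0.47) and Dnajb11 (-0.47) were the 3 members past the threshold. Dnajc3 (-0.48, adjusted p = 0.0872), Ero1lb (-0.57, 0.0882) and Atf6 (-0.32, 0.384) were then not, each smaller by more than its SE than before (-0.88, -0.87 and -0.75, SE 0.17, 0.19 and 0.19 before and 0.14, 0.17 and 0.18 after). Of the 10 calls, that of Txndc5 alone held when any 1 library was left out, where the largest adjusted p was 0.0667 for Dnajc3, 0.0618 for Pdia4, 0.0742 for Dnajb11, 0.13 for Ero1lb and 0.174 for Atf6.

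Neighbouring parts of the secretory pathway had calls in both directions and none of these lists passed the camera test. Their medians were below 0, at -0.17 for ER translocation, -0.12 for N-linked glycosylation and -0.15 for ER to Golgi transport. In that order 18 of 26, 21 of 35 and 25 of 36 members were negative. With fry, which does not set a list against other genes, their adjusted p were 0.0119, 0.027 and 0.0271. Of 26 ER translocation genes, 2 were higher, the short translocon genes Sec61g (0.51) and Sec61b (0.44), and 3 lower, Ssr3 (-0.51), Srpr (-0.48) and Tram1 (-0.45) (list adjusted p = 0.131). Adjusted over the list alone 4 were higher and 8 lower. Of 35 N-linked glycosylation genes, 2 were higher, Mogs (2.17) and Dpm3 (0.59), and 3 lower, the sialyltransferase gene St6gal1 (164 ± 20.9 against 334 ± 28.2) and the oligosaccharyltransferase genes Stt3b (-0.94) and Stt3a (-0.61) (list adjusted p = 0.129; 2 higher and 6 lower adjusted over the list alone). Of 36 ER to Golgi transport genes, Cope was higher (0.46) and Mia3 (-1.14) and Arcn1 (-0.83) lower (list adjusted p = 0.0528; 1 higher and 4 lower adjusted over the list alone). After the correction Sec61g, Mogs, St6gal1, Stt3b and Arcn1 kept adjusted p under 0.05, and the ER translocation gene Sec11c (-0.32 before, -0.46 after) gained it. Sec61b (0.15), Ssr3 (-0.31), Srpr (-0.31), Tram1 (-0.17), Dpm3 (0.21), Stt3a (-0.32) and Cope (0.27) became smaller by more than their SE (0.10 to 0.14 before and 0.07 to 0.11 after) and lost the call. Mia3 lost it at -0.89 (adjusted p = 0.0907), a change of less than its SE (0.28 before and 0.26 after). Mogs, St6gal1 and Stt3b kept the call when any 1 library was left out, as did Arcn1, and each of the 5 ER translocation genes missed it without at least 1 library.

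Ribosomal protein genes were higher in IgG1 cells, with 54 of 78 past the threshold, 0 lower and all 78 positive (median 0.54, camera adjusted p = 1.54e-41; adjusted p = 0.277 with an estimated correlation, which was 0.685). Adjusted over the list alone, 72 were higher. Examples were Rpl39 (1904 ± 184 against 1079 ± 138), Rpl30 (0.86) and Rpl26 (0.81). Nuclear genes of oxidative phosphorylation were higher in 25 of 55 cases and lower in 0 (median 0.43, adjusted p = 3.52e-23; adjusted p = 0.265 with an estimated correlation), or 42 higher and 1 lower adjusted over the list alone. Among them were the complex I genes Ndufb8 (1548 ± 218 against 855 ± 116) and Ndufs8 (0.73) and the ATP synthase genes Atp5e (0.79) and Atp5l (0.79). Of 36 proteasome genes 11 were higher and 0 lower (median 0.20, adjusted p = 1.38e-06; adjusted p = 0.224 with an estimated correlation), or 14 higher adjusted over the list alone, including Psmb3 (1023 ± 131 against 584 ± 16.0), Psma7 (0.62) and the immunoproteasome genes Psmb8 (1651 ± 38.9 against 1064 ± 62.1) and Psmb10 (0.65). The 3 lists had median lengths of 773, 755 and 1367 nt, and their corrected medians were 0.27, 0.25 and 0.20, with 23, 10 and 4 members past the threshold. After the correction Rpl30, Rpl26, Psma7 and Psmb10 were no longer past it, at 0.65, 0.48, 0.48 and 0.46, each smaller by more than its SE (0.19, 0.21, 0.13 and 0.15 before and 0.20, 0.19, 0.12 and 0.14 after). The proteasome median was 0.00 after quantile normalization and -0.03 after rescaling without Jchain, while the ribosomal median was 0.19 and 0.31 under these scalings and that of oxidative phosphorylation 0.13 and 0.20, lower than in the main fit. Of the 54, 25 and 11 calls in these lists 8, 7 and 2 held when any 1 library was left out.

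**Figure D3:**
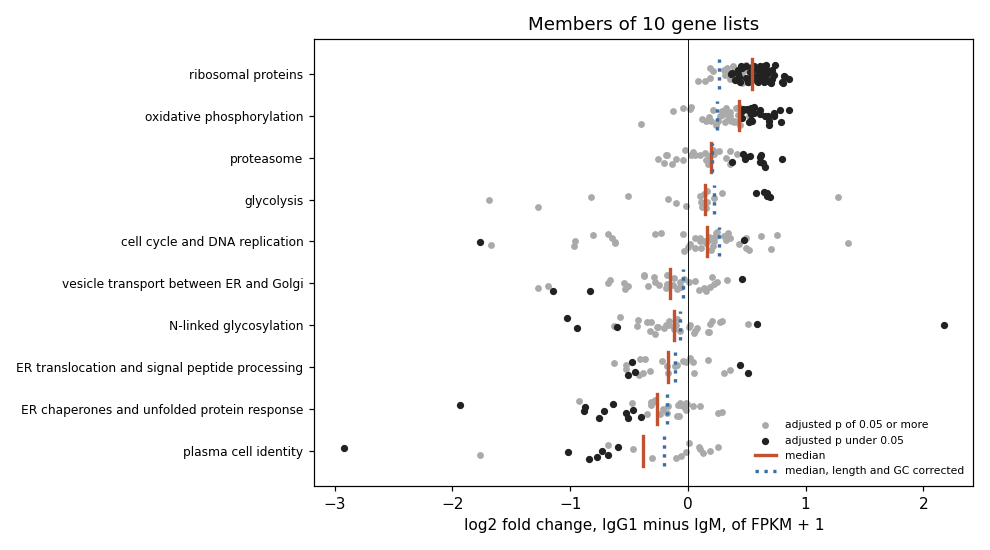
Log2 fold changes (horizontal axis, IgG1 minus IgM of FPKM + 1) of the tested members of 10 gene lists, black where adjusted p was under 0.05. Solid orange lines mark the medians (0.54 for ribosomal proteins, -0.38 for plasma cell identity) and dotted blue lines the medians after the length and GC correction (0.27 and -0.20).

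In metabolism, 5 of 22 glycolysis genes were higher and 0 lower (camera adjusted p = 0.0606; 6 higher and 1 lower adjusted over the list alone), including Gapdh (0.70), Eno1 (0.67), Ldha (0.67) and Tpi1 (0.65), all of which kept the threshold after the correction. When 1 library was left out, the adjusted p went up to 0.0987 for Gapdh, 0.106 for Eno1 and 0.146 for Ldha, and that of Tpi1 to 0.0471. With fry the glycolysis list had an adjusted p of 0.0429. The list's median was 0.15 before and 0.22 after the correction, where the list passed camera (adjusted p = 0.0154) but not with an estimated correlation (adjusted p = 0.35, and 0.277 before the correction). Of 20 amino acid transport and ATF4 target genes, the serine synthesis gene Phgdh (0.68) and Shmt2 (0.60) were higher and the glutamine transporter gene Slc38a2 (-1.13) lower, adjusted p = 0.207 for the list. Of 31 sterol and fatty acid synthesis genes, Mvd (0.90) was higher and Insig1 (-0.95) lower. Adjusted over the list alone these counts were 3 and 1, and 1 and 2. After the correction Slc38a2 was at -0.75 (SE 0.29 before and 0.26 after), smaller by more than its SE, and no longer past the threshold. Mvd (0.71, SE 0.24 and 0.22, adjusted p = 0.11) and Shmt2 (0.53, SE 0.16 and 0.13, adjusted p = 0.0529) also missed it, though they changed by less than their SE. Each of the calls in these 2 lists missed the threshold without at least 1 library.

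Survival genes moved in both directions, with 2 of 23 higher and 3 lower, also adjusted over the list alone. The list's median was -0.06, and its adjusted p was 0.343 with camera and 0.00742 with fry. Mcl1 (1.65, SE 0.32, adjusted p = 0.0135) and Bcl2l1 (1.12, SE 0.24, adjusted p = 0.0197) were higher, and Bcl2l11, which encodes the pro-apoptotic protein BIM, was lower at 45.0 ± 7.82 against 112 ± 14.9 (-1.30, SE 0.17, adjusted p = 0.00389), beside Tnfrsf17 and Tnfrsf13b. After the correction Mcl1, Bcl2l1 and Bcl2l11 were at 1.62, 1.10 and -1.15, all with adjusted p under 0.05. Leaving out 1 library raised the adjusted p to as much as 0.0688 for Mcl1, 0.101 for Bcl2l1 and 0.198 for Tnfrsf13b, and to 0.0296 for Bcl2l11.

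Among B cell genes, Cd79b (1378 ± 151 against 885 ± 68.9) was higher in IgG1 cells, 1 of 17 B cell identity genes past the threshold (list adjusted p = 0.556; 3 higher and 4 lower adjusted over the list alone), while Cd79a was at 347 against 390 (adjusted p = 0.445). Of 26 receptor signalling genes, Cd79b was higher and Ptpn6 and Ptprc, which encodes the phosphatase CD45 (23.5 ± 16.1 against 69.9 ± 3.84), were lower, also adjusted over the list alone. The germinal centre gene Mef2b was higher (0.93), as 1 of 12 (2 adjusted over the list alone), and Cd74, the invariant chain, was lower (-0.45), as 1 of 12 antigen presentation genes (also adjusted over the list alone). Ikzf3 (-1.25) and Irf4 were the 2 of 20 switch-associated regulators past the threshold, both lower, also adjusted over the list alone. Cxcr3 (1.96, SE 0.35, adjusted p = 0.0104) was 1 of 21 homing genes past it (2 adjusted over the list alone), with a largest adjusted p of 0.0505 when 1 library was left out. After the correction Mef2b (0.55, adjusted p = 0.087, SE 0.17 before and 0.16 after) was smaller by more than its SE and no longer past the threshold. Cd79b and Ptpn6 kept the call when any 1 library was left out, and Ptprc, Mef2b, Cd74, Ikzf3, Irf4 and Cxcr3 did not.

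In cytokine, interferon and stress lists, Il13ra1 (5.42 ± 1.51 against 19.5 ± 3.06) was 1 of 24 JAK-STAT genes past the threshold, Isg15 (-1.06) was lower and Ifitm3 (0.66) higher among 27 interferon response genes, and Lgals1 (0.62) was higher among 9 effector molecules. Jund (1.16) and Btg2 (0.47) were higher and Zfp36 (-0.76) lower among 20 immediate early genes. Adjusted over the list alone these lists had 0 higher and 1 lower, 2 and 2, 2 and 1, and 2 and 2. Of 44 cell cycle genes Pcna (0.48) was higher and Mki67 (10.7 ± 6.51 against 35.9 ± 7.68) lower, or 7 higher and 5 lower adjusted over the list alone. The list's median was 0.16 (camera adjusted p = 0.131) and 0.27 after the correction, where the list passed camera upwards (adjusted p = 0.0034) but not with an estimated correlation (adjusted p = 0.362, and 0.568 before the correction). Each of the calls of Il13ra1, Isg15, Ifitm3, Lgals1, Jund, Btg2, Zfp36, Pcna and Mki67 missed the threshold without at least 1 library. Of 28 autophagy and lysosome genes 0 were past the threshold with limma, adjusted over all genes or over the list alone (1 higher and 3 lower at an unadjusted p under 0.05), and the most abundant were Ctsz (1252 against 1454) and Gabarap (466 against 411). After the correction Ctsz passed the threshold as lower (-0.22 before and -0.40 after, adjusted p = 0.0301), as did the interferon response gene Ifi27l2a (-0.08 and -0.45). Ifitm3 (0.40), Lgals1 (0.34) and Jund (0.76) were then no longer past it, each smaller by more than its SE (0.15, 0.11 and 0.23 before and 0.14, 0.09 and 0.21 after).

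The genes with the largest fold changes outside these lists were, on the lower side, Pls1 (7.41 to 15.9 in IgM libraries and 0 to 0.976 in IgG1 libraries), Actr3b (11.7 to 14.8 and 0 to 1.73), Samsn1 (-3.01), Lrrn3 (6.87 ± 4.11 against 50.6 ± 3.31), Gpr155 (-2.81), Ccser2 (-2.45), the scavenger receptor gene Cd36 (4.25 ± 2.1 against 25.3 ± 4.26), Sh3bp2 (-2.31) and Gpr171 (-2.31). AW011738 and Zfp82 were at 5.62 to 8.01 and 5.20 to 8.15 in IgM libraries and were listed at 0 in 2 and 1 of the IgG1 libraries. The zeros of Actr3b and AW011738 fell in IgG1 libraries 2 and 3, that of Pls1 in library 3 and that of Zfp82 in library 2. These 2 libraries had the most tested genes at 0 (243 and 288), and how far that lowered these genes was not tested. On the higher side were Zmynd19 (17.2 ± 2.53 against 1.88 ± 1.52), Ube2m (2.60), Itgb5 (2.59), Adap1 (2.48), Csnk1g2 (2.43) and Ankrd13a (2.43). BC021614 was listed at 0 in the 3 IgM libraries and at 6.02, 7.50 and 7.86 in IgG1 libraries 1 to 3. For Alyref, Mtch1, Dapk3, Snx20 and Arf6, also higher in IgG1, IgM library 3 stood apart from the other 2 IgM libraries. Its FPKM were 95.1, 50.1, 55.9, 67.5 and 84.4, against at most 11.2 in IgM libraries 1 and 2 and at least 83.7 in the IgG1 libraries. After the length and GC correction Dapk3, Snx20 and Arf6 went from 2.91, 2.61 and 2.498 (SE 0.68, 0.61 and 0.60) to 2.61, 2.40 and 2.26 (SE 0.67, 0.60 and 0.60), by less than their SE, and missed the threshold with adjusted p of 0.0582, 0.0545 and 0.0664. When any 1 library was left out, Pls1, Actr3b, Lrrn3, Gpr155, Cd36, Sh3bp2, Gpr171, Zmynd19, BC021614 and Mtch1 kept adjusted p under 0.05. Samsn1, Ccser2, AW011738, Zfp82, Ube2m, Itgb5, Adap1, Csnk1g2, Ankrd13a, Alyref, Dapk3, Snx20 and Arf6 did not, with a largest adjusted p from 0.0521 for Ube2m to 0.143 for Arf6.

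Apart from Cd68 and Bst2, the tested markers of other cell types had mean FPKM of at most 12.03 in either group. The most abundant tested T cell genes were Lck (0.950 against 1.61) and Cd4 (1.21 against 0.653), and Prf1 (NK cells), Cxcr2 (neutrophils), Flt3 (dendritic cells), Hba-a1 (erythroid cells), Itgb3 (platelets) and Pecam1 (endothelium) were at 5.00 against 2.37, 1.33 against 0.843, 2.26 against 1.13, 2.09 against 1.80, 2.62 against 2.82 and 8.16 against 6.67. The dendritic cell list also holds Bst2 (310 against 328), which plasma cells express. Of 8 tested macrophage genes 0 were past the threshold with limma adjusted over all genes (0 higher and 3 lower at an unadjusted p under 0.05), and 3 were lower adjusted over the list alone, and the highest were Cd68 (38.3 against 57.8, adjusted p = 0.0598) and Hmox1 (12 against 7.75). After the correction Cd68 was past the threshold as lower (-0.59 before and -0.75 after, adjusted p = 0.036). The Y-linked genes Eif2s3y (21.9 against 24.8) and Ddx3y (9.14 against 10.7) were expressed in both groups.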

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

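The length and GC correction and cyclic loess were chosen after the data were seen. The list medians for plasma cell identity, ER chaperones, ribosomal proteins and oxidative phosphorylation kept their direction and their camera call in every fit with the preset correlation, and no named gene past the threshold changed direction. Counts of higher, lower, 2-fold higher and 2-fold lower genes (387, 160, 86 and 86) were 2, 4, 1 and 3 without the filter, 3, 5, 3 and 5 without the intensity trend, and 174, 377, 48 and 187 after rescaling without Jchain. Quantile normalization gave 188 higher and cyclic loess 182. The length and GC correction gave 189 higher, 81 lower and 47 lower at 2-fold. For the calls it ended, the median size went from 0.66 to 0.44 with a median SE of 0.15 before and 0.14 after. Of these 305 calls 223 became smaller by at least their SE and 82 did not, and 61 had an unadjusted p that the main fit would still have called, so smaller changes explain many of the ended calls and not all. Leaving out 1 library gave 78 to 394 higher, 30 to 251 lower, 17 to 116 2-fold higher and 21 to 167 2-fold lower. For the other settings the cause was not tested. Of 25 lists 5 passed camera, 7 after the length and GC correction (cell cycle and glycolysis in addition, neither with an estimated correlation), 8 without the filter, 8 after rescaling, 10 with fry, which tests each list without setting it against other genes, and 0 with an estimated correlation. There the adjusted p for medians of -0.38 (plasma cell identity), -0.26 (ER chaperones), 0.43 (oxidative phosphorylation), 0.20 (proteasome) and 0.54 (ribosomal proteins) were 0.24, 0.265, 0.265, 0.224 and 0.277. The estimated correlations of these lists were, in that order, 0.00946, 0.098, 0.283, 0.0174 and 0.685, against the preset of 0.01. For plasma cell identity and the proteasome the estimate was near the preset, so it does not by itself explain the higher adjusted p. The proteasome median was 0.0021 after quantile normalization (adjusted p = 0.411), 0.0017 after cyclic loess (0.486) and -0.0315 after rescaling. The replicate block gave 586 calls in place of 547, and 83 of 86 named genes kept theirs. Deviations of libraries with the same number correlated at 0.10, -0.03 and -0.00 across genes, so the numbers were not read as pairs. Of 86 named genes past the threshold, 57 kept it after the length and GC correction, 29 without IgM library 1, 5 without the trend and 3 without the filter. No symbol was repeated and immunoglobulin genes were not analysed here, so keeping rows apart and the share of constant-region genes were not run. The immunoglobulin share could not be computed. The share of Jchain in summed FPKM, computed in its place, averaged 1.79% in IgG1 and 3.52% in IgM cells. It was 1.554% to 1.932% in the IgG1 libraries and 3.275% to 3.912% in the IgM libraries. The Jchain share therefore stayed lower in IgG1 when any 1 library was left out. Depth was known only as an estimate.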

Other observations

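Tests list by list of expression level and library scale for ribosomal protein, oxidative phosphorylation and proteasome genes were chosen after those results were seen. For the 3 lists together, the bounds were set before the tests were run, but these were the 3 lists that camera called higher. The genes in the next paragraph were chosen after their values were seen.

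Outside the rule for named genes, several abundant genes differed with limma in all 6 fits without 1 library. Trp53inp1, a stress-induced p53 target, was at 103 ± 15.8 in IgG1 and 292 ± 54.8 in IgM cells (log2 fold change -1.48, adjusted p = 0.00279). Mdm2, the ubiquitin ligase for p53, was at 20.7 ± 3.49 and 56.7 ± 10.8 (-1.41, adjusted p = 0.00515). Pou2af1, a B cell coactivator, was at 281 and 474 (-0.75, adjusted p = 0.00474). The small GTPase genes Rab30 (-1.56) and Rraga (-1.88) were lower, and Crip1 (1.05), Cdc34 (1.91), Ckap4 (1.77) and Lars2 (1.07) were higher. All of these kept adjusted p under 0.05 after the length and GC correction.

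Because Mdm2 and Trp53inp1 are both p53 targets, lower expression of p53 targets as a set was a hypothesis. The other 21 tested targets had a median of 0.0592 (SD between members 0.66) and did not pass limma's camera as a set, with 1 higher and 0 lower past the threshold. That argues against a lower level of the whole set, and the cause of the drop in this pair stays open.

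With 547 genes past the threshold, the real grouping called more than any of the other 9 splits of the 6 libraries, of which the highest called 1. As 1 of 10 splits was as large, the real one itself, the design has too few splits for a share under 0.05. Each of the other 9 splits put IgM and IgG1 libraries together. Any steady difference between the groups, the length trend included, then raises the spread and lowers the calls. The contrast of 547 with 1 therefore does not tell isotype from such a trend. After removal of each library's length and GC trend 42.5% of the calls with a known length remained, so that trend may account for part of the calls. It separates the IgG1 from the IgM libraries in the same way as the isotype, and whether it arose in the preparation of the RNA or libraries or in the cells cannot be read from these data.

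Among the plasma cell identity and ER chaperone genes lower in IgG1 cells, 2 were tested singly, Tnfrsf17 and Txndc5. They had the smallest adjusted p of their lists (1.23e-06 each), so they do not stand for the other members. A difference in preparation that coincides with isotype was not tested. For Tnfrsf17 and Txndc5 the corrected fold changes were -3.11 and -1.87, and without any 1 library the smaller of the pair was at most -1.90, so neither the length and GC trend nor a single library accounts for them. For the lists as a whole, none of 10000 random lists matched on expression had a median as low (percentile 0). The median over both lists' members was -0.22 after median centring and -0.46 after quantile normalization. These values argue against expression level and library scale. A percentile this low was not particular to these lists. ER translocation and ER to Golgi transport also stood at 0, and N-linked glycosylation at 0.05. The random lists were not matched on transcript length. They could also hold ribosomal and oxidative phosphorylation genes, which were higher in IgG1 cells, so the percentiles may be lower than without them. The length and GC trend stays open for the lists, since the corrected median of -0.19 (SD 0.05 over fits without 1 library, -0.29 before) lay between the bounds set for either reading. Isotype, the difference the design names, was not tested apart from these and stays open too.

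For the higher level of ribosomal protein, oxidative phosphorylation and proteasome genes, the median over the members was 0.46 before and 0.24 after the length and GC correction (SD 0.03). List by list it went from 0.54 to 0.27 and from 0.43 to 0.25, but was 0.20 before and after for the proteasome. The trend as fitted may thus account for part of the difference in the first 2 lists and not for all of it. The correction did not use the authors' transcript lengths and was not combined with the other scalings. It also removed each library's mean deviation over the genes used to fit it, which is a change of scale. The median of the genes in the fit was -0.05 before and 0.03 after. Across genes, the fold change went up with mean expression (Spearman rho 0.279, genes not being independent replicates), and against random lists matched on expression the ribosomal median stood at percentile 100, oxidative phosphorylation at 98.0 and the proteasome at 35.5, so the test of the 3 lists together did not decide. Each random list left out only the tested list's own members. Those for the proteasome could therefore hold ribosomal and oxidative phosphorylation genes, also higher in IgG1. The proteasome median lay inside the range of its random lists, so a difference of expression level stays possible there. The ribosomal median (0.54) lay above the upper bound of its random lists (0.41) by more than its SD over fits without 1 library (0.07). Such fits share most of their libraries, so SDs over them understate the spread between libraries. Oxidative phosphorylation lay too close to the upper bound of its random lists (0.43 against 0.42) to decide. Library scale was not decided for the 3 lists together, whose median was 0.54 after median centring but 0.15 after quantile normalization. List by list, the lowest median over these scalings and rescaling without Jchain was 0.19 for ribosomal proteins (SD 0.03 over fits without 1 library) and 0.13 for oxidative phosphorylation (SD 0.02), which argues against scale as the whole cause there and leaves it open as part. For the proteasome it was -0.03 (SD 0.03), against 0.28 after median centring, so scale cannot be told apart from a change in those genes. A biological difference by isotype remains open and untested.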
